A study of Aspergillus niger with 11 samples.

How the data were processed

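RNA was sequenced from 11 libraries of Aspergillus niger strain DS03043, a filamentous fungus grown as a fed-batch culture under oxygen limitation. Per the labels, the fermenter held 5 L, was stirred at 375 rpm at 34 °C and pH 4.5, received 1 volume of air per volume of broth per minute, and stood under an overpressure of 0.05 MPa. The labels place each library in 1 of 4 growth phases, which are the exponential phase (n = 3), the early limited phase (n = 3), the middle limited phase (n = 3) and the late limited phase (n = 2). They list the sampling times of 18, 24, 42 and 66 h for the series and not per library, so the times were matched to the phases in chronological order. The design text speaks of triplicates, and 2 libraries of the late phase were analysed here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

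The authors deposited FPKM values (fragments scaled to the length of the transcript and to the mapped total), 1 value per gene and library, for 10445 genes in the same order at all 4 times. Per the labels' protocols, broth was frozen in liquid nitrogen straight after sampling and total RNA was made into libraries with the standard Illumina method. Per the submitters' processing notes, RSEM was used; its version, the aligner, the genome build and the gene annotation are not given in the sources used here. No scaling between libraries is recorded. FPKM divides by the length of the gene model and by the mapped total, so a few very abundant transcripts can shift all other values of a library.

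The depth was read from the values. In most genes the low values were whole multiples of a step, the FPKM that 1 read is worth. It was recovered with a tolerance of 0.06 for 7848 genes, or 90.2% of the 8697 genes above 0 in at least 2 libraries. In these genes, 99.79% of the low values of 66 h replicate 2 and 100% of those in the other libraries lay within 0.1 of a whole number of reads. Among 6760 genes above 0 in at least 4 libraries, 87.5% had such a step, against 1.1% after each value had been multiplied by a random factor of 1 to 2. Relative to the shallowest library, the depth was 1.21, 1.13 and 1.08 in the 18 h libraries and 1.11, 1.02 and 1.00 in the 24 h libraries. It was 1.38, 1.43 and 1.39 at 42 h and 1.59 and 1.50 at 66 h. Over the 7848 genes with a step, a library held 16815 to 23381 reads. Whether the values were computed on all reads sequenced is not given in the sources used here, so these numbers describe the deposited values. The median FPKM of 1 read over these genes was 8.58 to 13.6, and 58.8% to 64.7% of the genes with a step had 0 or 1 read in a library.

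Gene symbols were taken from a RefSeq gene table of assembly ASM285v2, which was used for names and the order of neighbouring genes, and none of its coordinates are given because the build of the authors' values is not given in the sources used here. Of the gene identifiers, 10417 matched that table and 28 did not, and 102 (0.98%) carried a symbol. The other genes are named by locus.

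Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, and fold changes are on that scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 2 libraries were tested (8693 genes). A single fit with a mean per time, all 11 libraries, and an empirical Bayes variance with a trend on the mean level gave the 5 comparisons and an F test of any difference between the 4 times. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all genes tested. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

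The fit was tested on simulated reads with the depths of these libraries, a dispersion of 0.02 and 200 changed genes. For genes with a mean FPKM of at least 100, it recovered 7 of 8 4-fold changes in a simulated comparison of 24 h with 18 h. The numbers were 7 of 10 for 42 h with 18 h, 4 of 11 for 66 h with 18 h, 10 of 10 for 42 h with 24 h and 4 of 8 for 66 h with 42 h. For 2-fold changes at that level they were 1 of 10, 0 of 14, 1 of 12, 1 of 7 and 2 of 8, in the same order. These are few genes, so differences between the comparisons are not interpreted. Under a mean FPKM of 30, the 4-fold changes recovered were 0 of 43, 0 of 43, 0 of 44, 0 of 47 and 1 of 43. Of the genes called, 5 of 29, 4 of 24, 9 of 28, 2 of 23 and 13 of 33 had not been changed. With a mean FPKM of at least 30 these were 1 of 24, 0 of 19, 1 of 18, 1 of 22 and 2 of 21. For this reason the counts of genes with a mean FPKM of at least 30 over all libraries are given beside the counts over all genes.

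The tests, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. In each comparison the rule took the 8 genes with the largest rise and the 8 with the largest fall among called genes that carry a symbol, reach a mean FPKM of 10 in 1 of the groups and have no overlap between the libraries of both groups. It added anchor genes of starch use, secretion, respiration and central metabolism whatever their result; 13 of 25 are named by the table. Because few genes carry symbols, the rule gave between 0 and 4 called genes per comparison. Further loci were therefore chosen after their values were seen. These are up to 6 called loci per direction with a mean FPKM of at least 300 in 1 of the groups and no overlap between libraries, the loci with the highest FPKM, loci in runs of called neighbours, both amyA loci and ostA. In every called gene named below, all libraries of 1 group lay above all libraries of the other. Of 42 gene lists fixed beforehand, 2 matched a single gene each (nuo51 and bipA), so the planned list tests and the share of expression per list could not be computed. In their place 8 lists were put together from the symbols after these had been seen and tested with camera of limma, with a preset correlation of 0.01, where at least 5 members were tested. On the same lists fry of limma was run beside camera, and its p-values are given without adjustment over the lists.

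Replicates were compared before they were averaged. A chi-square test on recovered reads separated all 10 replicate pairs within groups (chi-square per degree of freedom 1.18 to 1.79), so no library was counted as a copy of another. The alternatives were a pseudocount of 0.1 or 5, no filter or a filter at an FPKM of 10, rescaling to a common sum (TPM), median-of-ratios scaling, quantile normalization, a variance without a trend, a fit with the replicate number as a block, a fit with only the 2 groups compared, an adjusted p under 0.01, a 2-fold minimum, an estimated correlation within lists, and leaving out each library in turn. Alternatives chosen after seeing the data were reads thinned to the depth of the shallowest library, voom weights on read numbers, and only genes with a mean FPKM of at least 30. Genes without a recovered step, such as glaA, pkiA, PrtT, bipA, sspB and An02g11627, were not thinned. For voom these genes were given the median step, so their voom results do not rest on recovered reads.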

Results

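Transcript levels were measured by RNA sequencing at 4 times of an oxygen-limited fed-batch fermentation of Aspergillus niger DS03043. The aim was to follow how the fungus adapts to low oxygen. No culture kept free of oxygen limitation to the later times was among the libraries. Differences between the times therefore cannot tell oxygen limitation from culture age or growth phase, and their link to oxygen was not tested. The exponential phase (18 h), the early limited phase (24 h) and the middle limited phase (42 h) had 3 libraries each, and the late limited phase (66 h) had 2. Libraries listed 5399 to 5959 of 10445 genes above 0, their FPKM summed to 968822 to 1100826, and the 10 most abundant genes of a library took 18.0% to 20.5% of the sum. The reads recovered from the values numbered 16815 to 23381 per library over 7848 genes, so that most of these genes rested on few reads. Genes without a recovered step, among them abundant ones such as glaA, An03g06560 and An02g11627, are not in these numbers, which are thus not the full depth. Whether all reads sequenced entered the values is not given in the sources used here. The median standard error of the log2 fold change of 42 h against 18 h was 0.24 for genes with a mean FPKM of at least 300 and 1.56 for genes at 10 to 30.

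**Figure D1:**
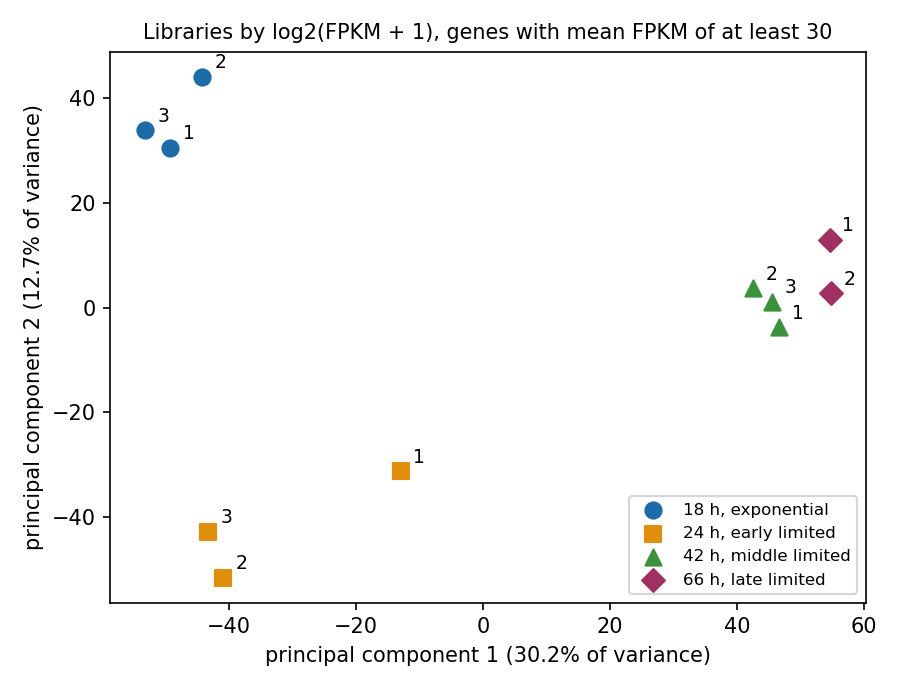
Principal components of the 11 libraries over 2933 genes with a mean FPKM of at least 30, each point a library, with colour and shape for the time of sampling and the number for the replicate. Component 1 (30.2% of variance) ran from between -53.3 and -44.3 at 18 h to between 42.6 and 54.8 at 42 and 66 h, with 24 h replicate 1 at -13.0 and the other 24 h libraries at -41.0 and -43.3.

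Levels of 698 of 8693 genes differed between the 4 times (limma F test, adjusted p under 0.05 after Benjamini-Hochberg adjustment). The count was 300 without a trend in the variance, 462 with the replicate number as a block and 1388 with voom weights. For 420 of the 698 (60.2%) the largest step between successive times lay between 24 and 42 h, for 200 (28.7%) between 18 and 24 h, and for 78 (11.2%) between 42 and 66 h. These steps span unequal lengths of time, for which the counts were not adjusted. The share with the largest step between 24 and 42 h was 56.0% without a trend, 62.8% with the block and 59.5% with voom weights. Among the 569 of the 698 with a mean FPKM of at least 30, the numbers were 368, 162 and 39. Over the genes with a mean FPKM of at least 30, the correlation of libraries across genes, which are not independent replicates, averaged 0.714 between 42 and 66 h against 0.734 within 42 h, and 0.609 between 18 and 24 h against 0.693 within 18 h and 0.657 within 24 h.

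The most abundant transcripts included loci without a symbol, which were chosen after their values were seen. An12g01290 made up 6.04% ± 0.55 of the summed FPKM at 18 h (SD, n = 3) and 3.63% ± 0.70 at 24 h (n = 3), but 0.011% ± 0.011 at 42 h (n = 3) and 0.010% ± 0.004 at 66 h (n = 2). An16g05680 made up 0.40% ± 0.06 at 18 h, 0.48% ± 0.40 at 24 h, 3.19% ± 0.34 at 42 h and 2.63% ± 0.39 at 66 h. Its 24 h mean is carried by replicate 1, at 10043 FPKM, while replicates 2 and 3 were at 2476 and 2949, below all 18 h libraries. An03g06560, the neighbour of the glucoamylase gene in the reference table, stood at 26130.1 ± 1569 FPKM at 18 h and 46160.3 ± 1758 at 42 h, a rise of 0.82 in log2 (SE 0.06, limma, Benjamini-Hochberg adjusted p = 3.2e-05). An12g03030 rose from 5357 ± 550 FPKM at 18 h to 27275 ± 8187 at 66 h (log2 fold change 2.32, SE 0.30, limma, Benjamini-Hochberg adjusted p = 0.00133). An16g04190 fell from 18658 ± 1027 to 9707 ± 402 FPKM between these times, a log2 fold change of -0.94 (SE 0.07, limma, Benjamini-Hochberg adjusted p = 7.62e-05). An02g11627 was listed at 38959 ± 6479 FPKM at 18 h and 27651 ± 3830 at 66 h and was called by limma in none of the 5 comparisons, but in the F test (adjusted p = 0.0414). For 66 h against 18 h it was called with the filter at an FPKM of 10 (0.0496) and with voom weights (0.000981), and for 66 h against 42 h with voom weights (0.0136). Without a trend in the variance, the calls of An03g06560 (adjusted p = 0.312 at 42 h), An12g03030 (0.0543) and An16g04190 (0.287) were lost.

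**Figure D2:**
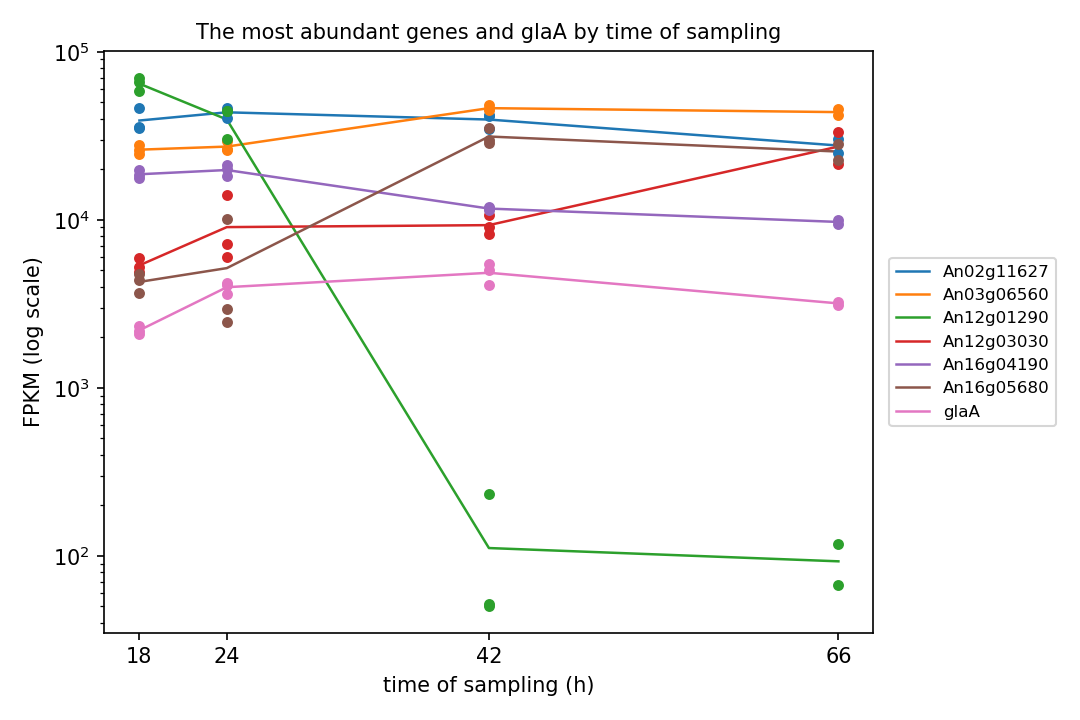
FPKM on a log axis against the time of sampling in hours for the most abundant loci, An03g06560 and glaA; points are libraries and lines join the means of each time. An12g01290 lies at a mean of 39522 FPKM at 24 h and 111 at 42 h, while An16g05680 goes from 10043, 2476 and 2949 FPKM in 24 h replicates 1, 2 and 3 to a mean of 31291 at 42 h.

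Between 18 and 24 h, the passage from the exponential to the early limited phase, glaA (An03g06550), which encodes the secreted starch-degrading enzyme glucoamylase, rose from 2200.4 ± 119 to 3969.9 ± 323 FPKM (SD, n = 3 each). This was a log2 fold change of 0.85 (SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.00503). pkiA (An07g08990), which encodes the glycolytic enzyme pyruvate kinase, fell from 1921 ± 479 to 776 ± 72.7 FPKM, a log2 fold change of -1.28 (SE 0.18, limma, Benjamini-Hochberg adjusted p = 0.00541). PrtT (An04g06940), the activator of extracellular protease genes, was at 267 ± 67.1 and 105 ± 46.5 FPKM and was not called (limma, Benjamini-Hochberg adjusted p = 0.0951), except without 24 h replicate 1 (0.0306). Among loci without a symbol, An16g06900 fell from 8333 ± 994 to 1535 ± 136 FPKM and An01g06160 from 2285 ± 397 to 333 ± 52.6, log2 fold changes of -2.44 and -2.77 (SE 0.14 and 0.29). An08g11610, An11g00560, An16g00890 and An18g01140 fell from means of 332 to 413 FPKM at 18 h, with log2 fold changes of -2.61 to -3.51. The calls of An11g00560 (adjusted p = 0.0588) and An18g01140 (0.0538) were lost without a trend in the variance. An12g00695 rose from 538 ± 295 to 2530.4 ± 481 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0177), a call that was lost without 24 h replicate 2 (0.0646) or replicate 3 (0.058), without a trend (0.149) and with only the libraries of these groups (0.0684). In all, 130 genes changed, of which 51 rose and 79 fell. Of these, 114 changed at least 2-fold, and 101 had a mean FPKM of at least 30 (34 rose, 67 fell). The count was 168 without 24 h replicate 1, 57 without a trend in the variance (29 rose, 28 fell), 71 with the replicate block (25 rose, 46 fell), 49 with only the libraries of these groups and 204 with voom weights. Without the trend neither glaA (adjusted p = 0.504) nor pkiA (0.325) was called, whereas both calls were kept in the other 22 settings, with adjusted p from 0.000506 and 0.000461 upwards.

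By 42 h, in the middle limited phase, glaA had risen to 4838 ± 694 FPKM, a log2 fold change of 1.13 against 18 h (SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.000295). sspB (An09g06590) fell from 1119 ± 76.6 to 412 ± 39.6 FPKM, a log2 fold change of -1.44 (SE 0.18, limma, Benjamini-Hochberg adjusted p = 0.000888). An12g01290 fell from 64522 ± 6001 to 111 ± 105 FPKM and An16g00100 from 10932 ± 101 to 172 ± 47.2, log2 fold changes of -9.55 and -6.01 (SE 0.48 and 0.22; limma, Benjamini-Hochberg adjusted p = 2.38e-06 and 2.62e-07). An01g06160 fell by 5.11 in log2 to 64.6 ± 5.6 FPKM, and An14g05180 fell by 3.52 in log2 from 2771 ± 351 to 241 ± 27.7. An14g02300 rose from 6.84 ± 5.94 to 677 ± 15.9 FPKM and An07g07940 from 22.1 ± 16.8 to 1031 ± 93.1, by 7.08 and 5.81 in log2 (SE 0.89 and 0.85). An15g02040 was listed at 0 in every 18 h library and at 556, 443 and 302 FPKM in the 42 h libraries (limma, Benjamini-Hochberg adjusted p = 0.00659). EPR (An08g04490) was listed at 0 in every 18 h library and at 31.01, 7.5 and 15.5 FPKM at 42 h (limma, Benjamini-Hochberg adjusted p = 0.0388). With 8 reads over all libraries, its call was lost without any of 18 h replicates 1, 2 and 3, 24 h replicates 2 and 3, and 42 h replicates 1 and 3 (adjusted p 0.0517 to 0.094). It was also lost without a filter (0.0583), with the replicate block (0.0607) and with only the libraries of these groups (0.0786). In all, 522 genes changed, 260 upwards and 262 downwards (301 and 227 with each library rescaled to the same FPKM sum). Of these, 471 changed at least 2-fold and 433 had a mean FPKM of at least 30 (207 rose, 226 fell). Without a trend in the variance the count was 249 (133 rose, 116 fell) and the calls of glaA (adjusted p = 0.182) and sspB (0.0931) were lost. Voom weights gave 928. Over the other 22 settings glaA and sspB kept their calls, with adjusted p from 1.2e-06 and 2.57e-05 upwards.

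**Figure D3:**
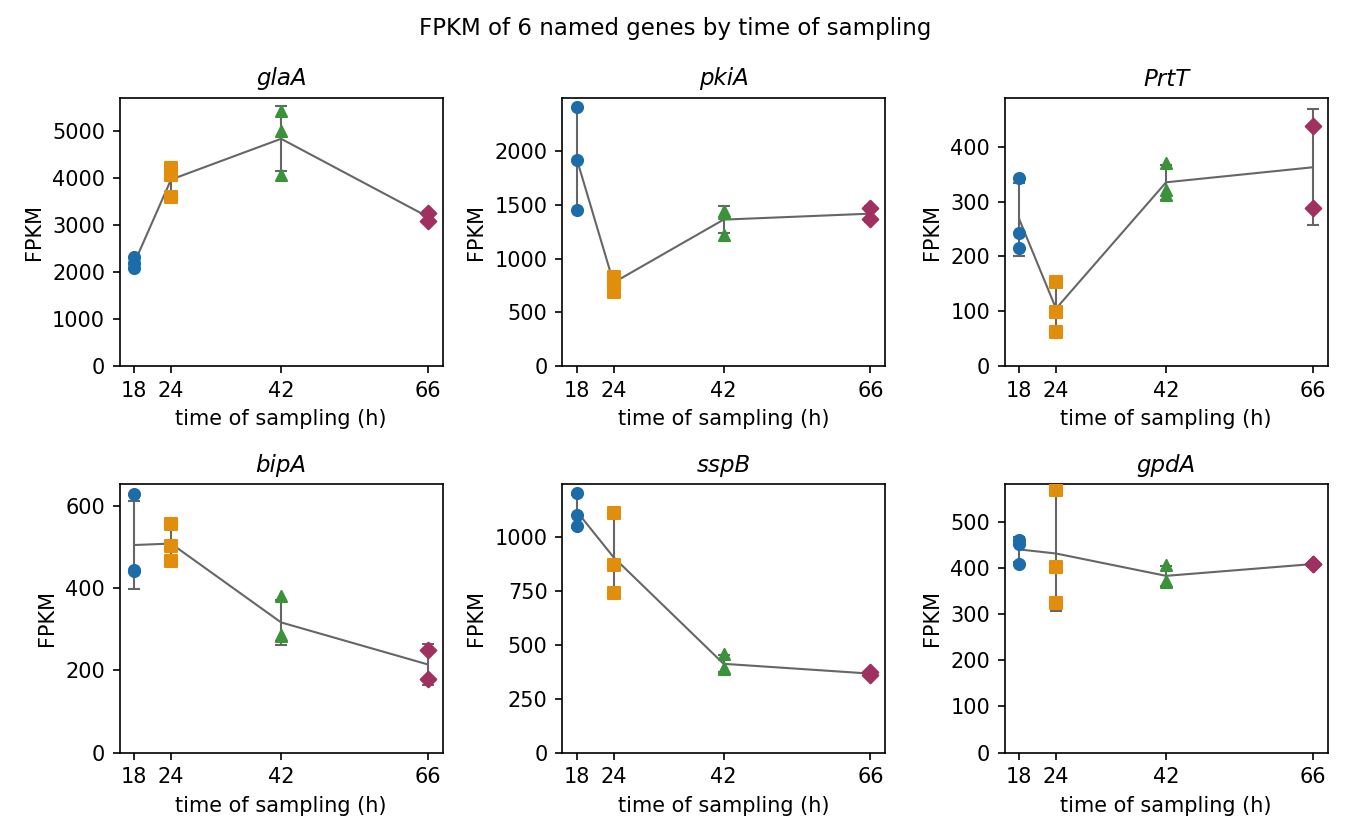
FPKM against the time of sampling in hours for glaA, pkiA, PrtT, bipA, sspB and gpdA, with points for libraries, lines through the means and bars for the SD (n = 3, and n = 2 at 66 h). glaA is at 2200.4 FPKM at 18 h and 4838 at 42 h, pkiA and PrtT have their lowest means at 24 h (776 and 105), and bipA and sspB are lowest at 66 h (214 and 366).

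At 66 h, in the late limited phase, bipA (An11g04180), the gene of the endoplasmic reticulum chaperone BiP, was at 214 ± 50.2 FPKM (SD, n = 2) against 504 ± 108 at 18 h (n = 3). It fell by 1.23 in log2 (SE 0.26, limma, Benjamini-Hochberg adjusted p = 0.018), and the call was lost without 66 h replicate 1 (adjusted p = 0.169), with only the libraries of these groups (0.0786) and with the replicate number as a block (0.0515). sspB was at 366 ± 7.85 FPKM, a log2 fold change of -1.61 from 18 h (SE 0.20, limma, Benjamini-Hochberg adjusted p = 0.00107). glaA was at 3179 ± 114 FPKM, 0.53 above 18 h in log2 (SE 0.13, limma, Benjamini-Hochberg adjusted p = 0.0359). This glaA call was lost without any of 18 h replicates 1, 2 and 3, 24 h replicate 2, 42 h replicate 1 or either 66 h library (adjusted p 0.0539 to 0.207), and with the replicate block (0.0688). An16g00100 was at 74.8 ± 8.91 FPKM and An12g01290 at 92.8 ± 36.1, log2 fold changes of -7.18 and -9.48 from 18 h (SE 0.25 and 0.54). An11g01700 fell from 455 ± 98.2 to 29.4 ± 14.9 FPKM (SE of the log2 fold change 0.46, limma, Benjamini-Hochberg adjusted p = 0.000599). An16g05680 rose by 2.58 in log2 to 25461 ± 3743 FPKM (SE 0.45, limma, Benjamini-Hochberg adjusted p = 0.00663), and its call was lost without 66 h replicate 1 (0.0629) and without a trend in the variance (0.077). An07g07940 rose to 1326 ± 30.5 FPKM and An14g02300 to 524 ± 166, by 6.18 and 6.67 in log2 (SE 0.95 and 1.00), and the An14g02300 call was lost with only the libraries of these groups (0.0583). An09g05020, at 590.2 ± 227 FPKM at 18 h, was listed at 0 in both 66 h libraries. In all, 525 genes changed (253 rose, 272 fell), 479 of them at least 2-fold and 433 with a mean FPKM of at least 30 (192 rose, 241 fell). The balance of rises and falls was not stable: 289 rose and 219 fell with each library rescaled to the same FPKM sum, 284 and 234 with median-of-ratios scaling, and 225 and 209 without 18 h replicate 1. The count was 220 without 66 h replicate 1 (68 rose, 152 fell) and 249 without 66 h replicate 2 (70 rose, 179 fell), which each leave 1 library at 66 h that is taken to vary like those of the other times. It was 251 without a trend in the variance (129 rose, 122 fell), where glaA, sspB and bipA were not called (adjusted p = 0.579, 0.0967 and 0.212), and 1018 with voom weights.

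From 24 to 42 h, within the limited phase, pkiA rose from 776 ± 72.7 to 1361 ± 126 FPKM, by 0.81 in log2 (SE 0.18, limma, Benjamini-Hochberg adjusted p = 0.0292). PrtT rose from 105 ± 46.5 to 335 ± 31.45 FPKM, by 1.75 in log2 (SE 0.35, limma, Benjamini-Hochberg adjusted p = 0.0162). sspB fell from 906 ± 188 to 412 ± 39.6 FPKM, a log2 fold change of -1.12 (SE 0.18, limma, Benjamini-Hochberg adjusted p = 0.0056). The pkiA call was lost without 18 h replicate 1, 24 h replicate 2 or 3, or any 42 h library (adjusted p 0.0509 to 0.104), and the PrtT call without 24 h replicate 2 or 3 or 42 h replicate 2 or 3 (0.0519 to 0.0643) and with only the libraries of these groups (0.0566). An12g01290 fell from 39522 ± 8039 to 111 ± 105 FPKM and An16g00100 from 10542 ± 2717 to 172 ± 47.2, log2 fold changes of -8.83 and -5.93 (SE 0.48 and 0.22). An02g07320 fell from 511 ± 180.1 to 45.5 ± 8.38 FPKM and An11g01690 from 1471 ± 199.9 to 164 ± 80.4, log2 fold changes of -3.40 and -3.28. An18g04350 rose by 3.14 in log2 (SE 0.58, limma, Benjamini-Hochberg adjusted p = 0.0119) to 2776 ± 102 FPKM from 1122 in 24 h replicate 1 and 176 and 155 in 24 h replicates 2 and 3. Its call was lost without 24 h replicate 2 (adjusted p = 0.0547), 42 h replicate 2 (0.0522) or 42 h replicate 3 (0.0527), without a trend (0.0819) and with only the libraries of these groups (0.0625). EPR was listed at 0 in all 24 h libraries as well (limma, Benjamini-Hochberg adjusted p = 0.0469), and its call was lost without any 18 h or 24 h library or 42 h replicate 1 or 3 (0.062 to 0.119). It was also lost with a pseudocount of 0.1 (0.0526), without a filter (0.067), after quantile normalization (0.0508), with the replicate block (0.0705) and with only the libraries of these groups (0.122). In all, 405 genes changed, of which 162 rose and 243 fell. A change of at least 2-fold was found for 346, and 342 had a mean FPKM of at least 30 (132 rose, 210 fell). With each library rescaled to the same FPKM sum, 195 genes rose and 185 fell. The count was 236 without 24 h replicate 2, 268 without 24 h replicate 3, 441 without 24 h replicate 1, 249 with only the libraries of these groups and 745 with voom weights. It was 132 without a trend, where pkiA, PrtT and sspB were not called (adjusted p = 0.378, 0.135 and 0.239).

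Between 42 and 66 h, within the limited phase, few genes changed. Both loci called among those with an FPKM of at least 300 fell. An06g00500 fell from 536 ± 33.1 to 190 ± 72.2 FPKM and An08g10990 from 1253 ± 103 to 457 ± 127 (SD, n = 3 and 2), log2 fold changes of -1.54 and -1.48 (SE 0.23 and 0.26). Their adjusted p were 0.0278 and 0.0412 (limma with Benjamini-Hochberg adjustment). An06g00500 was not called without 66 h replicate 2 (adjusted p = 0.138), and An08g10990 was not called without any 1 library other than 24 h replicates 1 and 3 (0.0537 to 0.347). Both calls were also lost without a trend (0.448 and 0.598), with the replicate block (0.132 and 0.19) and with only the libraries of these groups (0.439 each). That of An08g10990 was lost as well without a filter (0.0622), with the filter at an FPKM of 10 (0.0573) and with median-of-ratios scaling (0.0514). Of 91 genes with a symbol, limma called 0, with 8 at an unadjusted p under 0.05 and 1 called with voom weights. glaA was at 4838 ± 694 and 3179 ± 114 FPKM (log2 fold change -0.60, SE 0.13, limma, Benjamini-Hochberg adjusted p = 0.104) and was called without 42 h replicate 2 (0.0266) and with voom weights (0.0136). In all, 37 genes changed, and 570 had an unadjusted p under 0.05. Of the 37, 12 had a mean FPKM of at least 30 (1 rose, 11 fell), and the median of the mean FPKM of all 37 was 1.0. The count was 62 and 19 without 24 h replicates 1 and 2, 81, 95 and 82 without 42 h replicates 1, 2 and 3, and 18 and 17 without 66 h replicates 1 and 2. The planned test had 23 rises and 14 falls, but this balance turned. It was 1 and 17 without 66 h replicate 1, 0 and 17 without 66 h replicate 2, and 9 and 10 without 24 h replicate 2. It was 6 and 10 both without a filter and with the filter at an FPKM of 10, 0 and 4 with the replicate block, and 8 and 11 with voom weights. With only the libraries of these groups, limma called 0 genes, with 541 at an unadjusted p under 0.05, and voom weights on all libraries gave 19.

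Genes with symbols were also grouped by function, in lists made after the symbols had been seen. Of 5 starch genes tested, glaA rose at 24, 42 and 66 h against 18 h and the other 4 were called in none of the 5 comparisons. Of 25 tests of these genes, 12 had an unadjusted p under 0.05 in limma, with both amyA loci counted, and voom weights called 4. Both amyA loci (An12g06930 and An05g02100, alpha-amylase) had the same values in all libraries, so a change of 1 cannot be told from a change of the other. They were listed at 976 ± 51.5, 1452 ± 298, 1099.9 ± 20.5 and 819 ± 47 FPKM from 18 to 66 h. Without a call between 2 times, they were called in the F test over the 4 times (adjusted p = 0.0446). aglU, an alpha-glucosidase gene, was at 82.8 ± 6.3 FPKM at 18 h and 32.9 ± 1.27 at 66 h (limma, Benjamini-Hochberg adjusted p = 0.222), and amyR, the activator of starch genes, rested on 6 reads. Of 10 genes of the secretory pathway, bipA alone was called, at 66 h against 18 h. ostA (An02g14560), a subunit gene of the oligosaccharyltransferase, was at 319 FPKM at 24 h and 577 at 42 h (limma, Benjamini-Hochberg adjusted p = 0.0525) and was called in 7 of the alternatives, such as without 18 h replicate 3 (0.0171) and with each library rescaled to the same sum (0.0295). pdiA, for protein disulfide isomerase, rested on 25 reads. Of 12 regulator genes, PrtT alone was called, at 42 h against 24 h. Voom weights called 2 of 60 regulator tests over the 5 comparisons. Of these, 1 was at 66 h against 18 h, where PrtT was called in no setting. The carbon catabolite repressor gene creA rested on 16 reads. None of 13 tested genes for plant cell wall degradation, 8 protease genes or 6 genes of amino acid and nitrogen metabolism was called by limma in any comparison. Over the 5 comparisons, 0 of 65, 4 of 40 and 4 of 30 tests of these groups had an unadjusted p under 0.05, and voom weights called 0, 1 and 1. Among the proteases, the secreted acid protease gene pepA was at 4.48 ± 7.75 FPKM at 18 h and 44.8 ± 26.4 at 42 h (limma, Benjamini-Hochberg adjusted p = 0.138). It rested on 20 reads and was called there with voom weights (adjusted p = 0.0207). niaD (An08g05610), for nitrate reductase, was at 295 ± 77.1, 354 ± 46.5, 415 ± 75.3 and 334 ± 43.1 FPKM from 18 to 66 h. In the same group, argB, leu2A and trpC had log2 fold changes of -3.69, -3.41 and -3.05 at 66 h against 18 h (SE 1.60, 1.57 and 1.26). Those of niaD, gdhA and argA were 0.205, -0.047 and -0.188.

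Of 12 genes of central carbon metabolism, pkiA alone was called. The glycolytic gene gpdA, for glyceraldehyde-3-phosphate dehydrogenase, was at 439.6 ± 27.1, 431 ± 124, 382 ± 20.9 and 408 ± 0.08 FPKM from 18 to 66 h, with adjusted p from 0.673 upwards (limma with Benjamini-Hochberg adjustment). pyc, for pyruvate carboxylase, was at 49.5 ± 9.63 and 17.9 ± 7.84 FPKM at 18 and 66 h, and citA, for citrate synthase, at 66.0 ± 20.3 and 43.0 ± 28.9; neither was called. None of 4 respiratory genes was called by limma or with voom weights; 1 of 20 tests over the 5 comparisons had an unadjusted p under 0.05. aox1 (An11g04810), the alternative oxidase gene, was at 441 ± 92.6, 304 ± 66.7, 431 ± 142 and 454 ± 32.3 FPKM from 18 to 66 h, with log2 fold changes against 18 h of -0.53 (SE 0.29), -0.07 (SE 0.29) and 0.06 (SE 0.32). As a set, none of the 7 lists large enough for camera was called at an adjusted p under 0.05 in any comparison. At an unadjusted p under 0.05, camera gave 1 list at 24 h and 1 at 42 h against 18 h, the proteases both times (p = 0.0174 and 0.0152, Benjamini-Hochberg adjusted over the lists 0.122 and 0.107; adjusted p = 0.347 and 0.323 with an estimated correlation). It gave 1 list between 42 and 66 h, the starch genes (p = 0.00961, adjusted 0.0672, and adjusted p = 0.233 with an estimated correlation), and 0 in the others. For amino acid and nitrogen genes, fry gave unadjusted p = 0.00756 (42 h) and 0.00331 (66 h) against 18 h, and 0.00265 for 42 h against 24 h. For the proteases its p was 0.0229, 0.011 and 0.0369 at 24, 42 and 66 h against 18 h. For the starch genes its p was 0.0438 and 0.0327 at 24 and 42 h against 18 h, and 0.00268 between 42 and 66 h. In all other cases fry gave p above 0.05. The starch list reached 5 members only by counting both amyA loci, whose values were the same, so 1 measurement entered its tests 2 times. With camera, 1 list passed the adjusted threshold at 24 h without 18 h replicate 3, at 42 h against 18 h without 18 h replicate 3 or 42 h replicate 3, and between 42 and 66 h without 42 h replicate 1.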

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

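Of the tests here, the thinned reads, the voom weights, the restriction to genes with a mean FPKM of at least 30 and the symbol lists were chosen only after the results had been seen. In each setting compared gene by gene with the planned test, the calls found in both had the same direction, but the number of calls moved with the model of the variance, and the balance of rises and falls with the scaling, the variance and the libraries used. For 42 h against 18 h, 301 rose and 227 fell with each library rescaled to the same sum, against 260 and 262 in the planned test. For 66 h against 18 h, rescaling gave 289 and 219 and median-of-ratios scaling 284 and 234, against 253 and 272. Without a trend in the variance, rises and falls were 29 and 28 for 24 h against 18 h (planned 51 and 79), 133 and 116 for 42 h against 18 h and 129 and 122 for 66 h against 18 h. Without a 66 h library, the last were 68 and 152 (replicate 1) and 70 and 179 (replicate 2). Without a trend in the variance, the F test called 300 genes in place of 698, and the comparisons called 57 (24 h against 18 h), 249 (42 h against 18 h), 251 (66 h against 18 h), 132 (42 h against 24 h) and 67 (66 h against 42 h). The voom weights gave 1388, 204, 928, 1018, 745 and 19 in the same order, and an adjusted p under 0.01 gave 335, 55, 231, 241, 154 and 3, as a stricter threshold must. With only the libraries of the groups compared, and so fewer samples, the counts were 49 for 24 h against 18 h, 249 for 42 h against 24 h and 0 for 66 h against 42 h. For 66 h against 42 h the count was also 61 with a pseudocount of 0.1, 24 with 5, 16 without a filter, 16 with the filter at an FPKM of 10 and 12 for genes with a mean FPKM of at least 30; a pseudocount of 5 also called 1 symbol list there. Except where stated, the cause was not tested. Of 89 counts of genes, 60 stayed within 1.5 times.

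Leaving out 1 library in turn gave 532 to 741 genes in the F test, 103 to 168 for 24 h against 18 h, 380 to 577 for 42 h against 18 h, 220 to 570 for 66 h against 18 h, 236 to 441 for 42 h against 24 h and 17 to 95 for 66 h against 42 h. The 220 came without 66 h replicate 1, the 236 without 24 h replicate 2, the 17 without 66 h replicate 2 and the 95 without 42 h replicate 2. The number of symbol lists called was 0 to 1 for 24 h and 42 h against 18 h and for 66 h against 42 h, and 0 in the others. With the replicate number as a block, the F test called 462 genes and the comparisons 71 (24 h against 18 h) and 4 (66 h against 42 h). No pairing of the libraries by number was seen: deviations of same-numbered libraries correlated at -0.071 to 0.054 over 2933 genes, 0 of 15 pairs exceeded 0.1, and 2 of 11 libraries correlated best with their own number. Many of these genes rest on few reads, so a weak pairing could be missed.

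For single genes, 89 calls were followed through the settings. The variance without a trend ended 46 of them, the fit with only the groups compared 28, the replicate block 13 and a pseudocount of 0.1 ended 10. Without a trend, the variances of all genes are drawn towards 1 common level. For 42 h against 18 h, the median standard error was 1.56 at a mean FPKM of 10 to 30 and 0.24 at 300 or more. That setting can therefore raise the standard errors of abundant genes by design. Calls lost in it cannot tell a weak change from this property of the setting. Leaving out 1 library ended from 5 (24 h replicate 1) to 20 (24 h replicate 2). No call changed sign. An16g04190 at 42 h against 18 h had a log2 fold change of 0 after quantile normalization, which gives genes of the same rank the same value. In the comparison of 42 h with 18 h, 34.8% of 572 genes with a mean FPKM of at least 300 were called against 2.5% of 2213 genes at 10 to 30. In the simulated comparison of these times, the fit recovered 0 of 43 4-fold and 1 of 44 8-fold changes at a mean FPKM under 30, against 7 of 10 and 8 of 9 at 100 or more. In the simulation few reads thus lowered the number of calls at low levels; whether real changes are also fewer there was not tested.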

Other observations

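Of the tests reported in this part, those of mixing, of a mislabelled library, of voom weights between 42 and 66 h and of the placement of called genes were chosen only after the result had been seen. The loci were also chosen after their values were seen.

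Runs of adjacent loci in the reference order had fallen by 42 or 66 h, though not all at the same time. The loci An09g00530 to An09g00570 are 5 consecutive genes that all fell between 18 and 42 h (limma, Benjamini-Hochberg adjusted p from 0.000358 to 0.0179). An09g00570 went from 552 ± 79.4 FPKM at 18 h to 158 ± 45.1 at 42 h (SD, n = 3 each) and An09g00530 from 283 ± 30.6 to 61.8 ± 36.4, while An09g00540, An09g00550 and An09g00560, at means of 116, 32.2 and 65.2 FPKM at 18 h, were listed at 0 in every 42 h and 66 h library. At 24 h, An09g00550 was already listed at 0 (adjusted p = 0.00965) and An09g00570 was at 134 FPKM (0.00505), but the first call was lost with only the 18 and 24 h libraries (0.154) and the second without a trend in the variance (0.0895). An09g00540 was still at 90.6 FPKM (0.914). At 66 h, An09g00570 was at 273 FPKM and An09g00530 at 76.9, and neither was called against 18 h (adjusted p = 0.0982 and 0.0559), though An09g00530 was with voom weights (0.00338) and in 5 other alternatives (0.0322 to 0.0479). The An09g00530 call at 42 h was lost without 18 h replicate 1 or 3 or 42 h replicate 1 or 3 (adjusted p 0.0512 to 0.0625) and after thinning to equal depth (0.153). Without a trend in the variance, the calls of An09g00530 (0.0751) and An09g00570 (0.0601) at 42 h were lost. In another run, An08g10870 stood at 112 ± 36.8 FPKM at 18 h and 132 ± 16.97 at 24 h and was listed at 0 in all 42 h and 66 h libraries (limma, Benjamini-Hochberg adjusted p = 0.000783 for 66 h against 18 h). Its neighbours An08g10860 and An08g10880, at 21.8 ± 6.44 and 34.2 ± 13.8 FPKM at 18 h, were listed at 0 at 66 h and called there, but not without either 66 h library or without 18 h replicate 1 or 2, and An08g10880 also not without 18 h replicate 3 (adjusted p 0.053 to 0.188). Both calls were lost with the replicate block (0.0888 and 0.0787), and that of An08g10860 with only the 18 and 66 h libraries (0.0624).

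Between 18 and 42 h, 32 pairs of neighbouring genes were called in the same direction, against a mean of 13.1 when the called genes were shuffled 10000 times among genes of like level (highest 27, permutation p = 0.0001, the smallest that 10000 shuffles can give). Chance placement is thereby argued against, and 66 h against 18 h gave 28 pairs (mean 13.2, permutation p = 0.0002) and 42 h against 24 h gave 20 (mean 8.32, permutation p = 0.0008). For 24 h against 18 h there were 2 pairs (mean 0.84, permutation p = 0.2031), and for 66 h against 42 h there were 0. Reads shared between overlapping gene models remain open: 0.0% of the pairs overlap, but so do 0.0% of all 6071 neighbouring pairs in the reference table, and the models used by the authors are not given in the sources used here. Joint regulation of adjacent genes over the fermentation is a hypothesis that these values leave open and untested.

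Replicate 1 of 24 h lay between the other 24 h libraries and the later times. A set of 168 genes differed strongly between the other 24 h libraries and 42 h. Over these genes, replicate 1 stood at a median of 0.318 of the way to 42 h on the FPKM scale (95% bootstrap interval 0.286 to 0.348). The 24 h replicates 2 and 3 stood at -0.096 and -0.087, over 97 and 99 genes chosen for each in the same way. Their reference included replicate 1, which can itself lower these values, so they are not an independent contrast. Measured likewise against the other libraries of their own time, the 18 h libraries stood at 0.006 to 0.030 of the way to 42 h, and the 66 h libraries at 0.097 and 0.048 of the way to 18 h. A mislabelled 42 h library is argued against by the upper bound of 0.348. After thinning to equal depth the lower bound was 0.293. This cannot decide whether a difference in read number had a part, since genes without a recovered step were not thinned. The depths of 24 h replicates 1, 2 and 3 were also close (1.11, 1.02 and 1.00 relative to the shallowest library). A fixed part of later RNA or mycelium in the library is possible, and would place rising and falling genes at the same part of the way. They stood at about the same part (medians 0.301 and 0.340, difference 0.039, interval -0.028 to 0.114). Towards 66 h the difference was 0.063 (interval 0.015 to 0.138). This leaves out 0, but lies within the margin that counted as about the same part towards 42 h, a margin set after the result had been seen. The intervals of 18 h replicates 1 and 2 and 66 h replicate 2, which lay near their own times, were also within it. Those of 18 h replicate 3 and 66 h replicate 1 were not. The margin therefore cannot tell mixing from other explanations. All these intervals come from resampling the genes of a library, which are not independent replicates. Towards 18 h, 24 h replicate 1 stood at 0.149 of the way (interval 0.097 to 0.245, 56 genes), which no test here accounts for. A culture that was further along at sampling would be a biological explanation, which was not tested and stays open.

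Of the 37 genes called between 42 and 66 h, 25 (67.6%) had a mean FPKM under 30. With voom weights, 3 of the 37 (8.1%) were kept, although that test called 19 genes. These were 0 of the 25 and 3 of the 12 with a mean FPKM of at least 30. Since calls at both levels were lost, whole-read steps at low levels cannot be told apart from other sources of these calls. The simulated comparison of these times called 13 unchanged genes among 33. Differences between the middle and late limited phases stay open as well.

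In the F test over the 4 times, 1 of 100 splits of the libraries, the real one, called as many as 698 genes. This is the smallest share that 100 splits can give. It argues against a random division of the libraries as the source of the count. Because the replicates may come from 1 culture, the splits cannot tell an effect of time from 1 of culture or sampling. The highest of the other splits called 327, and it kept the 18 and 24 h libraries apart from those of 42 and 66 h, which points to that structure of the samples; the next called 38. For comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real count was 130 for 24 h against 18 h (1 of 10 splits as large, highest other 7), 522 for 42 h against 18 h (1 of 10, highest other 0) and 405 for 42 h against 24 h (1 of 10, highest other 3).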
